A study of Triticum aestivum and Triticum urartu and Aegilops speltoides with 12 samples.

How the data were processed

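Transcript levels were measured on 12 single-colour NimbleGen arrays, 2 for each of 6 plants: the diploids Triticum urartu (donor of the A genome), Aegilops speltoides (a relative of the B genome donor), Aegilops tauschii (donor of the D genome) and rye, a hexaploid wheat, and a hexaploid line with the 2BS.2RL translocation. Per the labels, each array held total RNA from the leaves and roots of 2 whole seedlings, harvested on day 10, and the 2 arrays of a group were independent biological replicates. Per the series design, each consensus sequence was read by 2 probes of 60 bp, with 52589 probe pairs designed. The deposited values hold more features than that (56855), and which of them have 2 probes was not examined. Ae. speltoides stands in here for the B genome donor. It is counted below among the progenitors and defines the B-specific class. How far its transcripts match those of the wheat B genome was not tested. Which slide held which sample is not given in the sources used here, so slide was not tested as a batch.

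The deposited values are linear intensity values, 1 for each feature and array, which the authors made with RMA, per the submitters' processing notes. The version of RMA and its steps are not given in the sources used here. That the scale is linear and not log2 was read from the values, whose median lay near 1600 on every array. Medians ranged from 1588 to 1667. Between-array normalization of this kind sets the arrays to nearly one distribution, so a change in the total amount of transcript cannot be seen. The number of arrays limits the precision.

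The table of raw probe intensities was not used, because its 12 value columns carry codes that match no label. The plan fixed before the data were examined had started from those raw values, with its own background correction, normalization and probe summary. The authors' values, planned as an alternative, therefore became the main source. The alternatives that need raw probes, and a planned test of disagreement between the probes of a pair, were not run. No feature ID matched the gene table used here (0 matches), so features carry their IDs only. The planned tests of gene lists and of chromosome arms were not run for the same reason.

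There were 56855 features, tested without a filter, and 8 control features, left out of the tests. All values were above 0, so log2 was taken without an offset. One group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom and 2.97 prior degrees of freedom). A feature was called where the Benjamini-Hochberg adjusted p was under 0.05 and the log2 difference was at least 1 in size, which is 2-fold. All adjusted p-values for single features come from limma.

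A feature was placed in a genome-specific class where it was called higher in 1 diploid than in each of the other 3. No hexaploid level was compared in that choice. The hexaploid arrays did enter the variance estimate behind it, which the test of translocation against wheat shares. Classes were then compared between the hexaploid lines by counts, by a two-sided Fisher exact test of the direction of the calls against all other called features, by camera with a preset correlation of 0.01 (and an estimated one), and by fry. Features share transcripts, unigenes and chromosomes and are not independent replicates, so Fisher and binomial p-values over features are too small. The prefix of the feature ID was taken as the species that the sequence came from. A probe can read a transcript of another species less well where the sequences differ. A called difference between plants can thus be one of probe match, and this was not separated from transcript level, also not in the genome-specific classes. That grouping was chosen after the IDs were seen. Chosen after the direction of the rye-specific calls was seen were the counts of rye-specific features above the progenitors, the levels of the called rye- and B-specific features in the other plants, and near-identical profiles, defined as features within 0.5 (root mean square, log2) over the 12 arrays, joined by single linkage.

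Each array carried 1 random control feature, used here as its background level. It is a single summarised value and no true detection limit, since 1 of the sGFP control features lay far below it. Where a feature lay at or below it on both arrays of the lower group, only a lower bound of the fold is given. The rule for the features named in the text, fixed before the data were examined, falls back without gene names on the 2 higher and 2 lower called features with the largest difference whose arrays do not overlap between the groups. Features named outside that rule are said to be.

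The procedure was tested on simulated data with the measured means and spreads of the 56855 features. In translocation against wheat, 67 of 100 features changed by a log2 of 1.5 and 94 of 100 changed by 3 were called in the right direction, and 7 of 168 calls were false. With equal groups 0 features entered a class, and 187 of the rye-specific features planted at a log2 of 3 were recovered. The simulated noise was normal, independent between features and, as in the model, of 1 spread per feature in all groups. In the data the SD of the replicate difference was 0.32 in wheat and 0.36 in translocation. It was 0.52 in rye and 0.59 in Ae. speltoides. The simulation cannot show false class members that such unequal spread may give.

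Alternatives covered scaling, filters on dim features, the variance model, the fold limit, the class definition and leaving out each array. Added after the data were seen were a floor and a scaling set by the random control, and an offset of 100. So were counting near-identical profiles once, and cyclic loess for rye against wheat and for the calls within classes. A first exploratory fit used the same model and thresholds, and none was changed after it.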

Results

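The arrays compared 4 diploids, a hexaploid wheat and a hexaploid line in which the long arm of wheat chromosome 2B is replaced by the long arm of rye chromosome 2R, as the name 2BS.2RL denotes. The series title names the purpose, the expression of transcripts specific to single wheat genomes and to rye in that line. Replicate arrays correlated across features at r = 0.968 to 0.990. The wheat and translocation arrays correlated with one another at 0.979 to 0.986, and all other pairs of groups at 0.826 to 0.904. Features are not independent replicates, and no p is attached to these values. The random control feature, read as background, averaged an intensity of 92.2 in wheat, 89.5 in translocation, 127 in T. urartu, 129 in Ae. tauschii, 155 in Ae. speltoides and 170 in rye (n = 2 each).

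The number of rye-specific features above the progenitors in the hexaploid lines bears on the labels and is given first. It was examined only after the direction of the rye-specific calls was seen. Signal on these features need not come from rye transcripts, since 41.5% of the class came from bread wheat sequences. Of 1648 rye-specific features, 249 and 237 lay at least 1 log2 above every A, B and D array on the arrays labelled wheat. On the arrays labelled translocation these were 226 and 223, and on the rye arrays 1410 and 1236. The gap of 11 between the nearest wheat and translocation arrays was no larger than the gap of 12 between the wheat arrays. In tests of single features, 54 rye-specific features were above all 3 progenitors in wheat alone and 22 in translocation alone (209 in both, exact binomial p = 0.00031, two-sided, over features that are not independent). The direction is opposite to that of a line that gains a rye arm. The labels were kept as deposited, and every direction below is that of the arrays labelled translocation or wheat.

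**Figure D1:**
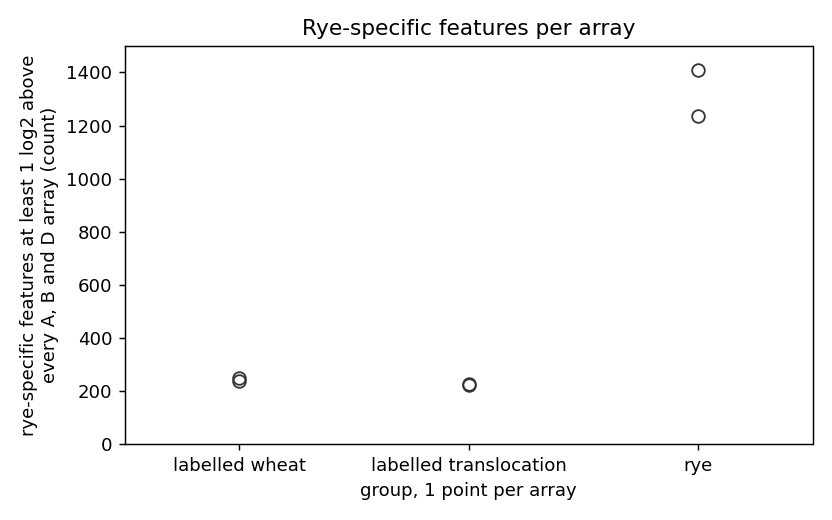
Number of the 1648 rye-specific features that lay at least 1 log2 above every A, B and D array, 1 point per array (y axis, count; x axis, group). The arrays labelled wheat hold 249 and 237, those labelled translocation 226 and 223, and the rye arrays 1410 and 1236.

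In the arrays labelled translocation, 188 features were higher and 177 lower than in those labelled wheat, 0.642% of all features, and 3327 had an unadjusted p under 0.05 in limma. The changes were large: 104 of the higher and 100 of the lower features differed by a log2 of at least 2, and of all 188 and 177 called features, the lower line lay at background in 66 and 48. Taestivum_ESTC049215 averaged 12.02 ± 0.20 (log2, SD, n = 2) in translocation and 4.54 ± 0.11, at background, in wheat, at least 45.2-fold higher (adjusted p = 1.02e-05). It reached 12.79 ± 0.45 in Ae. speltoides. Taestivum_ESTC017638 was at least 27.3-fold higher (11.30 ± 0.11 against 4.13 ± 0.10, adjusted p = 1.02e-05) and was between 4.57 and 5.42 in the 3 progenitors. Taestivum_ESTC037078 was at least 26.4-fold lower (3.59 ± 0.19 against 11.21 ± 0.33, adjusted p = 5.9e-06), and Taestivum_ESTC032217 at least 27.7-fold lower (4.02 ± 0.50 against 11.28 ± 0.05, adjusted p = 2.06e-05). Of the 365 called features, 228 were in the dimmest 25% by mean level over all 12 arrays, and 140 were called when these were left out. A feature high in few groups and at background in the rest can count as dim by that mean. In the line where they were higher, the 188 and 177 called features had median log2 levels of 10.11 and 9.99. Leaving out translocation replicate 2, wheat replicate 1 or wheat replicate 2 gave 212, 221 and 245 called features, with the lone array assumed to vary like the other groups.

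By sequence source, 50 of the 5731 features from rye sequences were lower in translocation and 7 higher, against 114 lower and 173 higher of the 42683 from bread wheat sequences. As a set, the rye-derived features did not pass the test (camera adjusted p = 0.506, median -0.01).

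Of the 4 diploids, rye correlated least with wheat (r = 0.837 to 0.842). In rye 6312 features were higher and 7913 lower than in wheat, 14225 of 56855. Features from rye sequences were higher in 1649 cases and lower in 99. As a set they passed the test (camera adjusted p = 3.06e-16, and adjusted p = 0.000571 with an estimated correlation). Probe match to rye and transcript level were not separated here. Scereale_ESTC003820 was at least 115-fold higher in rye (13.37 ± 0.12 against 4.28 ± 0.18, adjusted p = 8.36e-08) and Scereale_ESTC005951 at least 73.3-fold (12.72 ± 0.0015 against 3.93 ± 0.11, adjusted p = 9.34e-08). Taestivum_ESTC033205 was at least 17.4-fold lower (3.93 ± 0.31 against 11.53 ± 0.08, adjusted p = 9.34e-08) and Taestivum_ESTC038692 at least 15.0-fold (3.86 ± 0.55 against 11.31 ± 0.16, adjusted p = 4.12e-07). The split of these calls depended on the scaling: 2912 higher and 9378 lower with cyclic loess, and 1318 higher and 18761 lower when arrays were scaled to the random control. The median difference over all features was 0.19 as deposited, 0.04 with cyclic loess and -0.69 with that scaling, so the direction of small differences between rye and wheat is not settled.

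**Figure D2:**
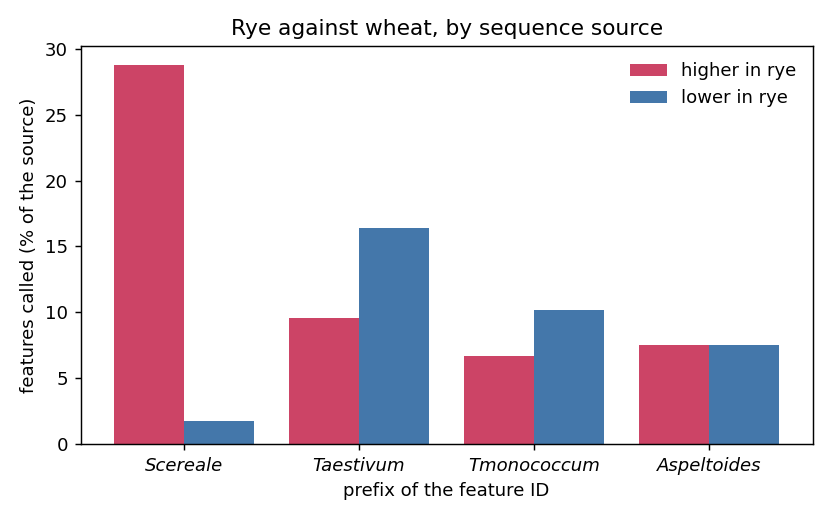
Share of features called higher or lower in rye than in wheat (y axis, percent of the features of a source) by the prefix of the feature ID (x axis). Of rye-derived features 28.8% were higher and 1.73% lower, and of those from bread wheat 9.56% and 16.4%.

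Between diploids, 9673 to 13191 features were called per pair. T. urartu against Ae. speltoides gave 5648 higher and 4692 lower, T. urartu against Ae. tauschii 5119 and 5338, and Ae. speltoides against Ae. tauschii 4281 and 5392. Rye gave 6004 higher and 7187 lower against T. urartu, 4948 and 5386 against Ae. speltoides, and 5366 and 7045 against Ae. tauschii. Features from T. monococcum, a close relative of T. urartu, were higher in T. urartu than in Ae. speltoides in 807 cases and lower in 170 (camera adjusted p = 0.000206, and adjusted p = 0.00716 with an estimated correlation). Features from Ae. speltoides sequences were lower in T. urartu than in Ae. speltoides in 268 cases and higher in 59. Both sets were mostly higher in the plant closest to their sequences, and probe match was not separated from transcript level.

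These comparisons placed 2032 features in the A-specific class, 1113 in the B-specific, 1974 in the D-specific and 1648 in the rye-specific class. Of the rye-specific features 53.0% came from rye sequences and 41.5% from bread wheat sequences. In wheat the median level of a class relative to its own diploid was -1.17 (log2) for A, -1.32 for B, -1.09 for D and -1.98 for rye. In translocation it was -1.17, -1.19, -1.07 and -2.004. With a class difference of at least 2 the classes held 843, 402, 871 and 620 features. Class sizes were not compared under cyclic loess or under scaling to the random control, which moved the rye calls most.

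In translocation against wheat, rye-specific features were called lower 58 times and higher 12 times, and B-specific features lower 11 times and higher 30 times. The A-specific class gave 14 lower and 14 higher, and the D-specific class 15 lower and 9 higher. Against all other called features, the odds of lower over higher were 7.11 for the rye-specific class (95% interval 3.59 to 15.2, Fisher exact adjusted p = 3.71e-10) and 0.350 for the B-specific class (0.153 to 0.748, Fisher exact adjusted p = 0.00871). The A- and D-specific classes did not pass this test (Fisher exact adjusted p = 1 and 0.273). Adjusted over the list alone, 72 rye-specific features were lower and 14 higher, and 13 B-specific features were lower and 36 higher. Near-identical profiles counted once, the rye-specific calls were 45 lower and 12 higher and the B-specific calls 11 lower and 27 higher.

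These calls are a small part of each class. As a whole, the rye-specific class did not pass the set test (camera adjusted p = 0.532, and adjusted p = 0.778 with an estimated correlation), with a median of 0.02 and a mean of -0.07, which differ in sign. The B-specific class was higher (median 0.05, camera adjusted p = 0.0477, and adjusted p = 0.0169 with an estimated correlation; fry adjusted p = 0.00969). Without wheat replicate 1 the rye-specific calls were 38 lower and 6 higher. Without wheat replicate 2 they were 39 and 7, and without translocation replicate 2 they were 39 and 5. With a class difference of at least 2 they were 43 and 5, and the B-specific calls 7 lower and 12 higher.

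**Figure D3:**
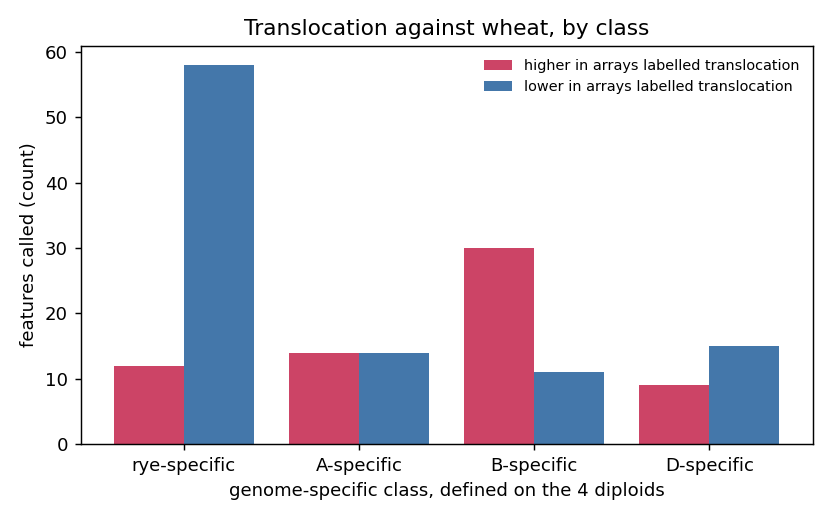
Features called in the arrays labelled translocation against those labelled wheat (y axis, count) by genome-specific class (x axis), higher and lower side by side. The rye-specific class holds 58 lower and 12 higher, and the B-specific class 11 lower and 30 higher.

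Levels in the other plants differed between the sets. The 58 rye-specific features lower in translocation had a median log2 level of 11.95 in rye, 10.01 in wheat and 6.98 in translocation. In wheat 31 of them averaged at least 1 log2 above all 3 progenitors, and in translocation 0 did. These were chosen for being lower in translocation, and the 12 called higher mirror them: their medians were 9.48 in rye, 7.25 in wheat and 9.66 in translocation, with 3 above all progenitors in wheat and 8 in translocation. In 21 of the 58, Ae. speltoides was itself called above T. urartu and Ae. tauschii. The 30 B-specific features higher in translocation had medians of 10.26 in Ae. speltoides, 9.52 in translocation and 6.43 in wheat, where 14 lay at background. The 11 called lower had medians of 11.30 in Ae. speltoides, 6.05 in translocation, where 5 lay at background, and 10.01 in wheat. Among rye-specific features, Atauschii_ESTC000032 was at least 15.9-fold lower in translocation (5.53 ± 0.0037 against 10.48 ± 0.04, adjusted p = 1.02e-05) and Scereale_ESTC002733 at least 15.6-fold (5.64 ± 0.11 against 10.45 ± 0.07, adjusted p = 0.000383). Both were near 13.1 in rye, and in Ae. speltoides they were 10.31 and 10.38. In the other direction, Taestivum_ESTC036947 was at least 8.21-fold higher in translocation (9.56 ± 0.14 against 5.33 ± 0.61, adjusted p = 0.00138) and Scereale_ESTC005231 at least 4.92-fold (8.83 ± 0.26 against 5.08 ± 0.06, adjusted p = 2.86e-05).

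Features that differed between rye and the mean of the 3 progenitors were common among those called between the hexaploid lines. Of the 177 features lower in translocation, 82 were higher in rye, against 13.1 for independent lists (odds ratio 11.01, 95% interval 8.08 to 15.0, Fisher exact adjusted p = 1.98e-44). A rye-specific feature lies at least 1 log2 above the progenitor mean by definition, and 58 of the 177 were rye-specific. This overlap is therefore no result separate from that of the rye-specific class. How many of the 82 are rye-specific was not counted. Of the 188 higher in translocation, 30 were higher in rye, against 13.9 (odds ratio 2.39, Fisher exact adjusted p = 8.4e-05), and 42 were lower in rye, against 19.8 (odds ratio 2.46, Fisher exact adjusted p = 4.19e-06). Of the 177 lower in translocation, 23 were lower in rye, against 18.6, which did not pass the test (Fisher exact adjusted p = 0.269). The 2 comparisons share no arrays, but both use the same fitted model and its variance estimate for each feature. A feature with a low estimate is likelier to be called in both, so the lists are not independent. The expected counts and Fisher tests do not allow for this, and its part in the overlap was not tested.

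Against the mean log2 level of its 3 progenitors, wheat was higher for 4358 features and lower for 1670. Median scaling gave 4388 and 1615. The random control was lower in wheat (6.53, log2) than in the progenitors (6.99 to 7.27). Cyclic loess and scaling to the random control, which moved the split between rye and wheat, were not counted here. How far this split depends on the scaling is thus not settled. Taestivum_ESTC037078 averaged 11.21 ± 0.33 in wheat and was at least 17.3-fold higher there (adjusted p = 1.9e-07), and Taestivum_ESTC038511 averaged 12.60 ± 0.27 and was at least 45.6-fold higher (adjusted p = 3.54e-07). Both lay at background on all 6 progenitor arrays. Taestivum_ESTC032653 (adjusted p = 9.16e-07) and Scereale_ESTC003696 (adjusted p = 8.32e-07) were lower. Both were at background in wheat and below the random control in 1 of the progenitors too, Ae. speltoides and Ae. tauschii respectively, so no fold is given. Of the features higher in wheat 2632 were above all 3 progenitors, and of those lower 1482 were below all 3, by group means at any margin and without a test. By at least 1 log2 these were 1604 and 294. Counted without a test, 4536 features were at least 1 log2 higher than the mean of logs and 2008 lower, and 2663 were at least 1 log2 higher than the mean of the linear levels and 3066 lower. Of the called features, 2609 higher and 1670 lower ones were also at least 1 log2 from the linear mean, which never lies below the mean of logs.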

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

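The test on the dim end was completed after its result was seen, with the brighter control features added.

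Control features for sGFP, which took no part in the tests of the report, gave signal above the random control on all 12 arrays in 4 of 7 cases. Their median intensities over the arrays were 2189, 279.9, 560.9 and 604.1, against 127 for the random control. What these features are meant to read is not given in the sources used here.

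The random control feature was higher on the rye arrays than on the wheat arrays, by 0.88 (log2). Wheat-derived features in the dimmest 25% also lay higher in rye, by a median of 0.50, against 0.06 for the other wheat-derived features, as they would with a normalization that lifts the dim end. Of 3 sGFP features brighter than the limit of 8.82, 2 that lay just above it (9.21 and 9.26) were higher in rye by 0.97 and 0.76, beyond their replicate SDs, and the brightest (11.15) by 0.44, within them. Whether normalization or a higher raw background in rye gave it stays open, and no biological explanation was tested.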

How the results depend on the processing

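Of 210 comparisons of a result with an alternative other than leaving out an array, 195 stayed and 15 moved. To stay meant the same side of the test or within 1.5 times, for counts of called features in the total and in each direction. Many of the 210 are single named features, picked for the largest differences, which could hardly move. The tally therefore overstates how stable the counts are. Translocation against wheat gave 140 features (66 higher and 74 lower) without the dimmest 25%, which had held 228 of the 365 calls, and 204 at a log2 of at least 2. Rye against wheat gave 12290 with cyclic loess and 20079 when scaled to the random control, both chosen after seeing the data. These moved in their split into higher and lower, and the cause was not tested. Wheat against its progenitors gave 5729 features on linear means, counted without a test, with 2663 higher and 3066 lower. A class difference of at least 2 leaves fewer features by construction: 843 A-, 402 B-, 871 D- and 620 rye-specific, with calls higher of 9, 12, 5 and 5, and calls lower of 7 in A and 7 in B. Leaving out each array gave 212 to 322 calls in translocation against wheat, 38 to 59 lower and 5 to 13 higher rye-specific, 5 to 14 both higher and lower A-specific, 5 to 10 higher and 9 to 15 lower D-specific, and 23 to 32 higher and 8 to 15 lower B-specific. Replicate numbers are not said to pair the samples, and deviations of same-numbered arrays correlated at -0.06 to 0.21. With the replicate block 366 features were called in translocation against wheat, 330 of them among the 365, and the other counts with the block stayed within 1.5 times. The filter at background used the single random control, as its planned 95th percentile needs several. Not run, for want of raw probes or gene names: no background correction, an offset of 0, the brighter or dimmer probe, median polish, the probe-pair, gene list and chromosome arm tests, and alternatives for the similarity of arrays. Signal over background limits the folds: many lower groups lay at background and give bounds only.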

Other observations

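All tests below were chosen after the results they bear on were seen. A test of the mean of logs fixed earlier, on counts against the linear mean, was set aside because that mean never lies below the mean of logs, which fixes the direction of the change.

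Among called features of translocation against wheat, 24 pairs had neighbouring ID numbers of one source, against 2.25 for random features (permutation p = 0.0001, the smallest that 10000 resamples can give). Of these pairs 100% moved the same way, as sequences of one transcript family may. Taestivum_ESTC037078 and Taestivum_ESTC037079 are such a pair. No sequence was examined. Of 114 Atauschii features, 84 had an Asquarrosa feature with a profile within 0.5 (root mean square, log2).

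Among called features, rye-specific ones were mostly lower (58 lower, 12 higher) and B-specific ones mostly higher (30 higher, 11 lower) in the arrays labelled translocation, while 82.2% of the rye-specific class lay within 0.5 log2 of no difference. Rye RNA mixed into the wheat samples was tested at 1 share only, 18.7%, the median over the 58 features called lower. Of 638 rye-specific features due to rise by 1 log2 at that share, 120 (18.8%) rose by at least 0.5. These values argue against mixing at that share. The 58 were picked for their difference, so the share may be too high, and a smaller one was not tested and stays open. Exchanged labels stay open. Each wheat array held more rye-specific features above the progenitors, but by 11, under the 12 between the wheat arrays. Such counts cannot decide, as they also differed between the lines in the A-specific class. There 655 and 669 features lay above every array of the other diploids in wheat, and 699 and 697 in translocation. The B-specific calls went the way of exchanged labels, as did rye-specific features above all progenitors in 1 line alone (54 in wheat, 22 in translocation). Correct labels stay open too, with rye chromatin also in the wheat line, as the share of rye-specific features higher in translocation was 0.728% against 0.574% of A- and D-specific features (Fisher exact p = 0.576), or with wheat signal from a B-genome arm absent from the translocation line. For the last, B-specific calls went the other way with near-identical profiles counted once (27 higher, 11 lower, exact binomial p = 0.0139). A class difference of at least 2 was required as well after this was seen. With it the calls again leaned higher but, being fewer, did not pass (12 higher, 7 lower, exact binomial p = 0.359). The B-specific class as a whole was also higher in translocation (camera adjusted p = 0.0477). The pedigrees of the lines are not given in the sources used here.

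More features were higher than lower in wheat against the mean of its progenitors. Where the 3 progenitor means lay within 1 log2, so that the linear mean exceeded the mean of logs by at most 0.08, the ratio of higher to lower was 1.71 among called features. Counted without a test it was 1.43 against the mean of logs and 1.23 against the linear mean. How much of the excess comes from the mean of logs stays open. By sequence source, all calls higher and lower were 3895 and 1267 for bread wheat, 192 and 149 for rye, and 208 and 160 for T. monococcum. They were 53 and 80 for Ae. speltoides, 5 and 8 for Asquarrosa, and 5 and 6 for Atauschii. The excess thus lay mostly in features from bread wheat sequences. Cyclic loess and scaling to the random control were not counted for this comparison. Neither probe match to each plant nor the biological explanation, a change of expression in the hexaploid, was tested.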
